A study of Mus musculus with 3 samples.

How the data were processed

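RNA of sorted spleen dendritic cells from male C57BL/6 mice was measured on 3 one-colour arrays, 1 each for normal mice and for mice at day 28 and day 63 of infection with Schistosoma japonicum. Per the labels, spleen cells were stained with antibodies to CD3e and CD11c and sorted, RNA was taken with Trizol, and Cy3-labelled cRNA was made from 1 µg with a Quick Amp kit. The sort gate, pooling of animals and the event from which days are counted are not given in the sources used here. Groups were taken from the sample labels.

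The deposited scanner files hold the intensity of each spot, per the file headers made with Agilent Feature Extraction 11.0.1.1 on array design 026655 at 5 micron pixels. Per the file headers these intensity values were background-subtracted and detrended within each array, and not scaled between arrays. All 3 arrays lay on 1 slide, at positions 1, 2 and 3, and were read in 1 scan, so slide and scan do not separate the groups, while position and group cannot be told apart. The authors' series matrix holds log2 values of the same arrays, 39485 entries, each column with a median of 6.23 and a 75th percentile of 8.86. Set against the scanner values of the same array, these deposited log2 values had Spearman correlations across probes of 0.998, 0.997 and 0.999 and Pearson correlations of 0.996, 0.996 and 0.993 for normal, day 28 and day 63. Their quantiles were equal in the 3 columns, so scale (log2), direction and the lack of centring per probe were settled from the values, and the tool the authors used for this step is not given in the sources used here.

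The depth of an array is given here as spots above background. Spots well above background numbered 32554, 32702 and 33892 of 43020 on the normal, day 28 and day 63 arrays, and no spot was saturated. The median signal was 79.5, 65.3 and 95.7 intensity units. Spots marked as outliers by the software (166, 547 and 451) were left out, which left 736 probes without a value on some array. Among 399 probes with 10 spots each, the median SD of replicate spots was 0.104, 0.0729 and 0.0861 on the log2 scale, over 298, 309 and 320 probes with at least 8 usable spots above background. For a ratio of 2 arrays this gave 0.127 for day 28 against normal, 0.135 for day 63 against normal and 0.113 for day 63 against day 28. These values cover spots on an array and not differences between animals, cells or hybridisations.

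The value of a spot was the log2 of its processed signal minus the array's 75th percentile of that quantity over non-control probes, and spots of a probe were averaged. The files hold no gene names, so probes were named by matching their RefSeq accessions, without versions, to a RefSeq gene table of assembly GRCm38.p6. Of 39429 probes, 27234 (69.1%) were named, for 20659 genes, and 12195 stayed unnamed here. The header names the array's design build as mm9, so no coordinates were used. A gene's value was that of its probe with the highest mean log2 value, which applied to 5476 genes with several probes, and 20401 genes had a value on the 3 arrays. A gene counted as measured in a comparison when well above background on at least 1 of the 2 arrays. Where 1 side was dim, it was replaced by the higher of its own value and a floor, and the ratio is given as "at least". The floor was the lowest averaged value on that array among probes with a share of at least 0.5 of their spots well above background. Genes were counted at 2-fold and, for description, at 4-fold.

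Before the data were examined, 20 gene lists and 13 lists of cell type markers, the rule for named genes and 10 alternatives for the counts were fixed. The gene lists were the conventional dendritic cell core, cDC1, cDC2 and plasmacytoid dendritic cell lists, MHC class II and class I presentation, costimulation and maturation, pattern recognition receptors, proinflammatory cytokines and chemokines, regulatory mediators, type 2 response, type I interferon, interferon-gamma, cell cycle, unfolded protein response, glycolysis, oxidative phosphorylation, ribosomal proteins, reference genes, and immediate early and dissociation stress. The marker lists were T cell, B cell, plasma cell, immunoglobulin constant regions, NK cell, neutrophil, eosinophil, monocyte, red pulp macrophage, erythroid, basophil and mast cell, platelet and megakaryocyte, and stromal and endothelial. A list's median was placed among 10000 random lists of equal size drawn from the same 20 bins of mean expression, if at least 3 members were measured.

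Named genes were the 10 genes with the largest ratio in each direction (5 for day 63 against day 28) that were well above background on both arrays, with the brighter side above the median of detected probes and all probes going the same way. Immunoglobulin and T cell receptor genes, provisional gene models and unnamed probes were left out of that ranking. To these were added up to 4 members of each list with the largest absolute log2 ratio, and always Itgax, Flt3, Zbtb46, Irf8, Irf4, Batf3, Siglech, H2-Ab1, Cd40, Cd80, Cd86, Ccr7, Cd274, Pdcd1lg2, Il10, Il12b, Cd3e, Actb and Gapdh. A few list members outside this rule, such as Siglec1 at day 28, were named after their values were seen.

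Alternatives were scaling to the array median, the 75th percentile over detected probes, quantile normalization, normexp background correction with an offset of 50 (limma 3.58.1 in R 4.3.3), the authors' series matrix, only genes above background on both arrays, no filter on dim probes, the mean of a gene's probes, outlier-marked spots kept and, for counts, a further threshold on the software's error. The mean signal of a spot was not used here and normexp was run on the median signal, a change from the plan. Counts without marker genes and counts of genes whose probes all went the same way were added after seeing the data, as were 5 further gene lists (a second neutrophil and a second basophil list, glucocorticoid response, Notch targets and hypoxia response). Overlap of the comparisons with the shared normal array was set against 100 simulations with spot error only.

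Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, with seed 20. The procedure was tested on simulated data for day 28 against normal with 16427 genes, of which 200 were changed. The simulated arrays were copies of the normal array with spot error only, so the test does not cover differences between animals, cells or hybridisations. All of the 50 genes made 3-fold higher, 50 made 3-fold lower, 50 made 4-fold higher and 50 made 4-fold lower were called (100% each), as were 10 of the 16227 other genes. A list of 20 of these other genes, shifted by 0.5, stood at percentile 100, and 1 of 40 random lists lay in the outer 2.5% on either side. No test, p-value or interval was computed, since each group had 1 array. The ratios of 1 gene are not reported here.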

Results

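Gene expression was measured in dendritic cells sorted from the spleens of male C57BL/6 mice. Dendritic cells take up antigen, present it to T cells and set the kind of T cell response that follows. There were 3 groups of mice with 1 array each: normal mice, mice at day 28 and mice at day 63 of infection with Schistosoma japonicum, a blood fluke whose eggs lodge in liver and gut. For the sort, spleen cells had been stained for CD11c, a surface protein of most dendritic cells, and for CD3e, a T cell protein. The gate, the number of mice behind an array and the event from which the days are counted are not given in the sources used here. The arrays read the brightness of Cy3-labelled cRNA at each spot, and 32554 of 43020 spots (75.7%) were well above background on the normal array, 32702 (76.0%) on the day 28 array and 33892 (78.8%) on the day 63 array. The 75th percentile of the signal, to which each array was scaled, was 478, 417 and 575 intensity units.

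With 1 array per group there were no replicates, so no test was run and no p-value is given, and the number of arrays limits the precision of every value. "Higher" and "lower" compare 2 arrays, and genes were counted at a fixed size of 2-fold. The error estimated by the scanner software for a ratio had a median of 0.20 on the log2 scale in each comparison, and covers spots only, not animals. The percentile of a gene list places its median among 10000 random lists of equal size matched on mean expression, and describes these arrays only.

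The comparison of day 28 with normal mice asked how the transcripts of spleen dendritic cells differed at the earlier time of infection. Interferon-induced genes stood far higher on the day 28 array: Ifi44 by 31.4-fold, and the type I interferon list as a whole by a median log2 ratio of 2.56. Genes of antigen presentation on MHC class II and of dendritic cell identity were lower, with H2-Aa, a chain of the class II molecule, 2.88-fold lower and Flt3, the growth factor receptor of the dendritic cell lineage, 2.45-fold lower. Transcripts of neutrophil granules and of plasma cells were much higher, such as Ngp by 41.7-fold and Jchain, the joining chain of secreted IgM and IgA, by 16.6-fold. Markers of red pulp macrophages, which clear old red blood cells, were lower, with Vcam1 6.03-fold lower.

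Of 16726 genes measured, 746 were at least 2-fold higher on the day 28 array and 700 at least 2-fold lower, 144 and 110 of them as bounds because 1 side was not well above background. Which direction held more genes depended on scaling. With scaling to the array median 877 were at least 2-fold higher and 564 at least 2-fold lower, and with the 75th percentile of detected probes 718 and 742. At least 4-fold differences were found for 183 and 78 genes. The largest ratios upward, among genes ranked by the rule for named genes, were those of Itgb2l (47.3-fold), Ngp, Ltf (31.7-fold), which encodes lactoferrin, Ifi44, Camp (25.6-fold), an antimicrobial peptide, Slfn3 (23.3-fold), Cfb (23.2-fold), complement factor B, Mpo (22.5-fold), the myeloperoxidase of granules, Iigp1 (18.4-fold) and Jchain. The largest downward were those of Agmo (25.5-fold lower), Calml4 (15.1-fold), Lyve1 (11.2-fold), Folr2 (9.24-fold), Kcnj16 (9.08-fold), Cdhr3 (8.85-fold), Cd209e (8.27-fold), Cd209d (8.06-fold), Gdf15 (7.82-fold) and Egr1 (7.20-fold). Slfn3, Cd209d and Cd209e belong to families of near-identical genes, so a probe may not tell their members apart.

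In the type I interferon list, 20 of 23 measured genes were at least 2-fold higher and none was 2-fold lower (percentile 100). Besides Ifi44 they included the antiviral genes Oasl2 (12.9-fold), Ifit3 (11.5-fold) and Rsad2 (10.5-fold). In the interferon-gamma list, 11 of 19 genes were higher, none was lower, and the median was 1.58 (percentile 100). Iigp1, a GTPase that attacks the vacuoles of pathogens, was 18.4-fold higher, Gbp6 11.1-fold, Gbp2 5.50-fold and Tgtp1 4.84-fold. The chemokine gene Cxcl10, an interferon target, was 5.71-fold higher. The MHC class I list was slightly higher, with a median of 0.39 (percentile 99.93) and 1 of 16 genes past 2-fold, the peptide transporter gene Tap1 (2.08-fold). The neutrophil markers were higher in the same comparison, by a median of 3.66.

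The MHC class II list had 8 of 15 genes at least 2-fold lower and none higher, with a median of −1.02 (percentile 0). H2-Oa was 3.00-fold lower, H2-Aa 2.88-fold, H2-DMb2 2.55-fold and H2-Eb2 2.41-fold, whereas H2-Ab1 had a log2 ratio of −0.24. The conventional dendritic cell core list had 6 of 18 genes lower and none higher, with a median of −0.47 (percentile 0). These included Klri1 (3.78-fold), Flt3, Ccr7 (2.17-fold), the receptor that guides dendritic cells into T cell zones, and Zbtb46 (2.07-fold), a transcription factor of conventional dendritic cells. The gene of CD11c, Itgax, a target of the sort, had a log2 ratio of −0.22. Markers of the CD8 subset (cDC1) had a median of −0.40 (percentile 0.23), with 3 of 14 genes lower: Cd8a (2.44-fold), Batf3 (2.34-fold), a transcription factor needed for this subset, and Tlr11 (2.01-fold). Irf8, another of its transcription factors, had a log2 ratio of −0.05. Markers of the CD11b subset (cDC2) had a median of −0.48 (percentile 0.03), with 4 of 13 lower: Esam (5.03-fold), an adhesion molecule of the Notch-dependent splenic subset, Cd209a (4.47-fold), Clec4a4 (2.68-fold) and Dtx1 (2.52-fold). Irf4, a transcription factor of that subset, had a log2 ratio of 0.16. Plasmacytoid dendritic cell markers had a median of −0.64 (percentile 0), with 3 of 16 lower, among them Lag3 (2.47-fold) and Ptprs (2.03-fold), while Siglech had a log2 ratio of 0.23. The B cell markers, of a cell type that also carries MHC class II, had a median of −0.18 (percentile 9.38), with 1 of 14 lower, the complement receptor gene Cr2 (2.27-fold). Red pulp macrophage markers and immediate early genes were lower in the same comparison, with medians of −1.65 and −1.57.

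The costimulation and maturation list had a median of −0.38 (percentile 0.07), with Fscn1, an actin-bundling protein of mature dendritic cells, 2.63-fold lower, Tnfsf9 2.28-fold lower and Il15ra 2.45-fold higher among 3 genes lower and 1 higher of 18. Log2 ratios were −0.31 for Cd40, 0.07 for Cd80, −0.97 for Cd86, 0.49 for Cd274, the gene of PD-L1, and −0.73 for Pdcd1lg2, the gene of PD-L2. Proinflammatory cytokines and chemokines had a median of −0.55 (percentile 0), with 5 of 18 genes lower and 1 higher. Ptgs2, the inducible cyclooxygenase, was 6.29-fold lower, Ccl2 2.64-fold lower and Tnf 2.43-fold lower, and Cxcl10 was the only gene at least 2-fold higher. Il12b was not measured in any comparison. Among regulatory mediators, 2 of 16 were higher, Arg2 by at least 4.50-fold and Lilrb4a by 2.33-fold, and 2 were lower, Arg1, an arginase typical of type 2 responses, by 3.48-fold and Aldh1a2 by 2.02-fold. The median of that list was 0.12 (percentile 93.1) and its sign differed between processing settings. Il10 had a log2 ratio of −0.14. The type 2 response list had a median of −0.11 (percentile 34.4), with Chil3 6.57-fold higher and 4 of 14 genes lower, such as Mrc1, the mannose receptor (6.68-fold), and Ccl24 (3.04-fold). The pattern recognition receptors had 4 of 25 genes higher, among them Clec4d (2.75-fold) and Ifih1 (2.68-fold), and 5 lower. Their median was 0.08 (percentile 94.5) and their mean −0.12.

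Immediate early and dissociation stress genes, which are switched on within minutes by signals or by tissue handling, were 2-fold lower for 11 of 14 members and higher for none, with a median of −1.57 (percentile 0). Egr1 was 7.20-fold lower, Fosb 5.69-fold, Hspa1a, a heat shock protein, 5.67-fold and Jun 4.81-fold. Cell cycle genes were higher for 17 of 25 members and lower for none, with a median of 1.71 (percentile 100): the spindle motor gene Kif11 by 6.74-fold, Plk1 by 4.83-fold, Mki67 by 4.57-fold and Rrm2 by 4.31-fold. Neutrophil markers, with a median of 3.66, were higher on the same array. In the unfolded protein response list 6 of 15 genes were higher, with a median of 0.33 (percentile 99.78): Derl3 by 16.1-fold, Creld2 by 3.08-fold, Pdia4 by 2.96-fold and Xbp1 by 2.44-fold. The plasma cell markers, which share Derl3 and Xbp1 with that list, had a median of 3.53. Glycolysis genes had a median of 0.23 (percentile 98.3), ribosomal protein genes −0.29 (percentile 0.18) and oxidative phosphorylation genes −0.09 (percentile 19.1), with no member past 2-fold. Reference genes had a median of −0.04 (percentile 39.4), whose sign differed between settings, with log2 ratios of 0.29 for Actb and 0.38 for Gapdh.

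Among markers of other cell types, 11 of 12 neutrophil genes (percentile 100) and 8 of 9 plasma cell genes (percentile 100) were at least 2-fold higher. The plasma cell genes included Tnfrsf17, the receptor BCMA (15.2-fold), and Mzb1 (13.1-fold). Basophil and mast cell markers were higher for 6 of 9 genes, with a median of 2.14 (percentile 100): the basophil proteases Prss34 by at least 53.5-fold and Mcpt8 by at least 24.1-fold, Hdc, which makes histamine, by 15.3-fold, and Gata2 by 6.72-fold. Monocyte markers had a median of 0.65 (percentile 100), with Fcgr1 6.07-fold and Ly6c1 4.29-fold higher among 3 of 10. Red pulp macrophage markers were lower for 10 of 14 genes and higher for 1, with a median of −1.65 (percentile 0). Besides Vcam1, the complement gene C1qa was 5.24-fold lower, Cd163 4.47-fold and Mertk 4.18-fold, while Siglec1, an interferon-inducible gene, had a log2 ratio of 1.43. NK cell markers had a median of 0.34 (percentile 99.55), with the granzyme genes Gzmb (5.51-fold) and Gzma (2.11-fold) higher among 12. T cell markers had a median of 0.16 (percentile 96.7) and a mean of −0.05, with Tcf7 and Trat1 lower (2.47-fold and 2.34-fold) among 15, and Cd3e, the T cell gene of the sort, had a log2 ratio of 0.11. Eosinophil markers had a median of −0.05 (percentile 57.1), whose sign differed between settings, and a mean of 0.39, with Prg2 10.1-fold higher, Epx at least 3.17-fold higher and Ccr3 4.02-fold lower. Erythroid markers had a median of 0.27 (percentile 99.1), stromal and endothelial markers 0.48 (percentile 99.89) and platelet markers −0.31 (percentile 26.9). Of these 3 lists only the platelet gene Ppbp passed 2-fold (2.34-fold lower).

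With normexp background correction, genes at least 2-fold higher at day 28 than in normal mice numbered 386 and genes at least 2-fold lower at day 28 than in normal mice 248, and Cd163, Arg1, Arg2, Cd8a, Lag3, Ptprs, Tlr11, Tnf, Aldh1a2, Gzma, Cr2, Trat1, Epx and Ppbp were under 2-fold, as was Cd8a with the mean of probes, Zbtb46 with scaling to the array median and Tap1 with quantile normalization. Medians with normexp were 1.09 for the basophil markers, 2.40 for the plasma cell markers and −0.24 for the proinflammatory list.

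**Figure D1:**
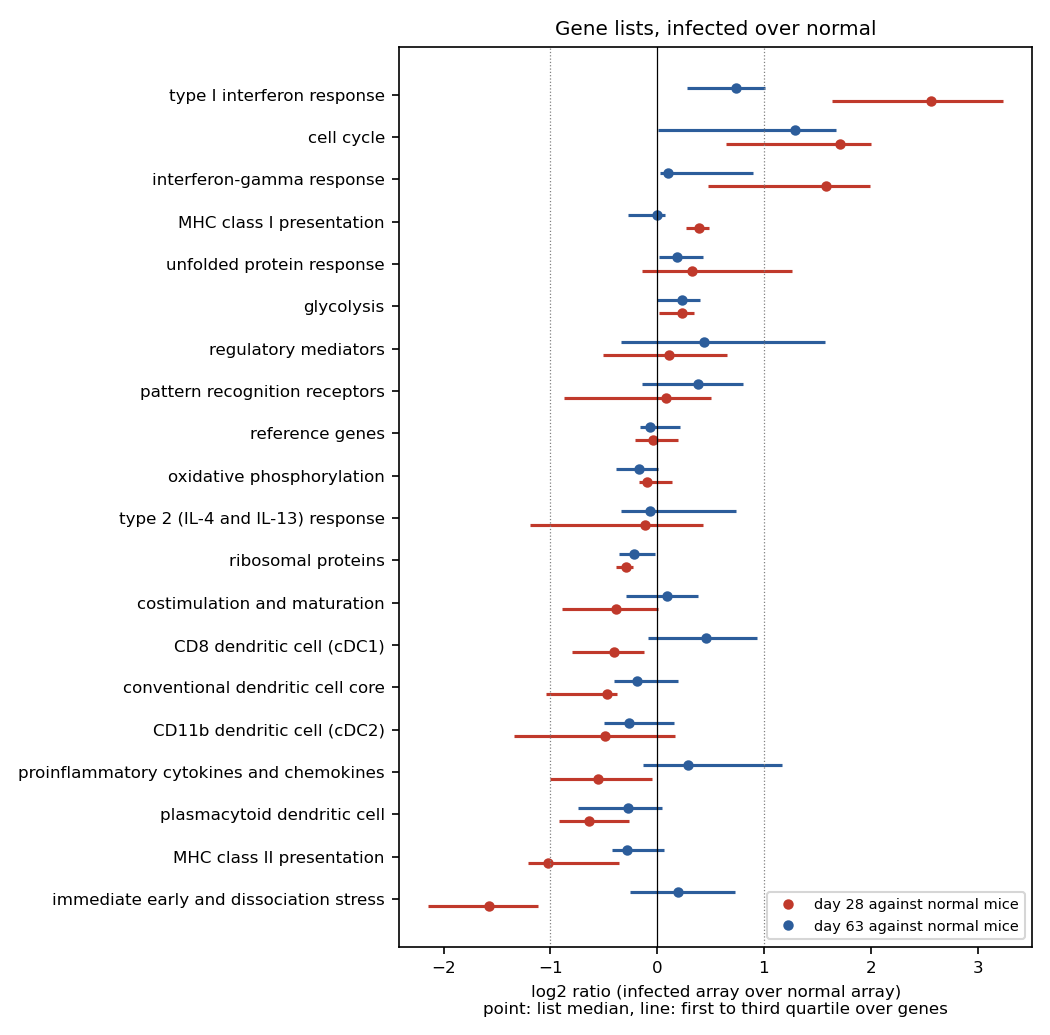
Median log2 ratio (points) and range from the first to the third quartile over genes (lines) of 20 gene lists, as the log2 ratio of an infected array over the normal array on the horizontal axis, with day 28 in red, day 63 in blue and dotted lines at 2-fold. The type I interferon list lies at 2.56 for day 28 and 0.73 for day 63, the cell cycle list at 1.71 and 1.30, and the immediate early list at −1.57 and 0.19.

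The comparison of day 63 with normal mice asked the same of the later time. Neutrophil and basophil transcripts were among the genes with the largest ratios: Mmp8, the neutrophil collagenase, was 92.7-fold higher, Ngp 53.4-fold and the basophil protease gene Prss34 at least 408-fold. Saa3, an acute-phase protein, was 116-fold higher and Arg1 19.2-fold. Genes of NK cells and of T cell receptor signalling were lower, such as the NK receptor gene Klra4 by 6.88-fold and the kinase gene Lck by 5.67-fold. The normal array already carried these transcripts, with 12 of 12 NK cell and 15 of 15 T cell markers well above background. Klra4 and Lck stood at log2 levels of 4.41 and 3.60 there. A smaller share of these cells at day 63 was not tested as a cause. The type I interferon list had a median of 0.73 with 6 of 23 genes at least 2-fold higher, the interferon-gamma list one of 0.11 with 3 of 19, and the cell cycle list one of 1.30 with 16 of 25. MHC class II genes had a median of −0.28, and none of the 15 was 2-fold lower.

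Of 16986 genes measured, 717 were at least 2-fold higher on the day 63 array and 524 at least 2-fold lower, 171 and 80 of them as bounds, and 151 and 66 differed at least 4-fold. Genes were ranked by the rule for named genes, which covers only genes well above background on both arrays. Bounds, such as that of Prss34, fall outside it. The largest ratios upward in that ranking were those of Saa3, Mmp8, Itgb2l (59.6-fold), Ngp, Cstdc4 (47.1-fold), Wfdc21 (46.2-fold), Stfa2l1 (43.3-fold), Chil3 (5.32 on the log2 scale), a chitinase-like protein, Lcn2 (34.9-fold), the iron-binding lipocalin of neutrophils, and Il1r2 (34.1-fold), the decoy receptor of interleukin-1. Cstdc4 and Stfa2l1 belong to the stefin A family, and Chil3 has a close relative, so their probes may read several copies. The largest downward in the ranking were those of Calml4 (10.2-fold lower), Hspa1a (8.25-fold), Spin2c (7.65-fold), Klra4, Cdhr3 (6.68-fold), Gzmm (6.62-fold), Klra8 (6.28-fold), Frmd5 (5.84-fold), Klre1 (5.82-fold) and Klrg1 (5.81-fold). Agmo was not well above background at day 63 and so was left out of the ranking. Its log2 level was −0.09 on the normal array and −5.62 on the day 63 array. Gzmm, Klra4, Klra8, Klre1 and Klrg1 are genes of cytotoxic lymphocytes, and the Klra genes are near-identical copies.

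All 12 neutrophil markers were at least 2-fold higher, with a median of 4.54 (percentile 100), Ltf by 30.3-fold. Basophil and mast cell markers were higher for 8 of 10 genes, with a median of 3.85 (percentile 100): besides Prss34, Mcpt8 by at least 134-fold, Fcer1a, a chain of the high-affinity IgE receptor, by at least 4.52 on the log2 scale, and Gata2 by 22.2-fold. Monocyte markers had a median of 0.58 (percentile 100), with 4 of 10 higher: Chil3, F13a1 (2.96-fold), Fcgr1 (2.11-fold) and Plac8 (2.03-fold). When spots marked as outliers by the scanner software were kept, that median was 0.24 and Plac8 was under 2-fold. NK cell markers were lower for 11 of 12 genes, with a median of −1.68 (percentile 0), among them Eomes (5.46-fold), a transcription factor of NK cells. T cell markers were lower for 9 of 15 and higher for none, with a median of −1.12 (percentile 0): besides Lck, the receptor chain gene Cd247 by 5.81-fold and Zap70 by 4.12-fold, genes that NK cells also use in part. Cd3e had a log2 ratio of −0.15. Red pulp macrophage markers had a median of −0.59 (percentile 0), with the iron exporter gene Slc40a1 2.84-fold, Axl 2.63-fold and C1qa 2.20-fold lower and Marco 2.18-fold higher among 14. B cell markers had a median of −0.22 (percentile 4.50), with Cr2 3.21-fold lower.

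Plasma cell markers had a median of 0.30 (percentile 98.7), with Derl3 3.39-fold, Sdc1, the gene of CD138, 2.19-fold and Mzb1 2.02-fold higher among 9. The unfolded protein response list had a median of 0.19 (percentile 98.8), with Derl3 as its only member past 2-fold. Eosinophil markers had a median of −0.12 (percentile 24.9), with Prg2 4.08-fold higher and Ccr3 2.09-fold lower. Erythroid markers had a median of 0.37 (percentile 99.4), with Car2 2.12-fold lower. Stromal and endothelial markers had a median of −0.57 (percentile 0.07), with Cdh5 2.47-fold higher. Platelet markers had a median of 0.34 (percentile 97.57), with Itga2b 3.11-fold and Treml1 2.27-fold higher, and the sign of that median was negative with normexp.

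Dendritic cell lists had medians nearer to 0 than the neutrophil and basophil lists. The core list had a median of −0.19 (percentile 5.29), with Klri1 2.15-fold lower among 18 genes, and log2 ratios of 0.37 for Flt3, −0.51 for Zbtb46, −0.58 for Itgax and −0.32 for Ccr7. The cDC1 markers had a median of 0.46 (percentile 100), with 3 of 14 higher: Tlr3, a sensor of double-stranded RNA (2.25-fold), Id2 (2.24-fold) and Gcsam (2.12-fold). Batf3 and Irf8 had log2 ratios of −0.09 and −0.12. The cDC2 markers had a median of −0.27 (percentile 1.08), with Esam 4.71-fold, Cd209a 3.72-fold and Dtx1 2.12-fold lower among 14, and Irf4 at −0.49. Plasmacytoid markers had a median of −0.27 (percentile 0.59), with Klk1 3.65-fold and Upb1 2.01-fold lower among 16, and Siglech at 0.18. The MHC class II list stood at percentile 1.39, with H2-Ab1 at −0.26. The MHC class I list had a median of 0.00 (percentile 84.6), whose sign differed between settings, and a mean of −0.08, with no gene past 2-fold. In the costimulation list the chemokine gene Ccl17 was at least 6.92-fold higher as the only one of 18 past 2-fold, and the median was 0.09 (percentile 93.5). Log2 ratios were −0.21 for Cd40, 0.35 for Cd80, 0.59 for Cd86, 0.50 for Cd274 and −0.33 for Pdcd1lg2.

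Regulatory mediators had 6 of 16 genes higher and none lower, with a median of 0.43 (percentile 100): Arg1, Arg2 by at least 7.33-fold, Il1rn, the interleukin-1 receptor antagonist, by 3.82-fold and Socs3 by 3.25-fold. Il10 had a log2 ratio of 0.62. Proinflammatory genes had a median of 0.29 (percentile 99.91), with 6 of 19 higher and 2 lower. The neutrophil chemokine gene Cxcl2 was 4.36-fold and Il6 4.30-fold higher, and Cxcl1 was 5.19-fold and Ccl5 3.95-fold lower. The pattern recognition receptors had a median of 0.39 (percentile 100), with Clec4d 5.08-fold and Clec4e 4.94-fold higher, 2 receptors common on myeloid cells. These gene groups stood beside neutrophil markers that were higher by a median of 4.54. In the type 2 response list Arg1, Chil3 and Ccl17 were higher, 3 of 14, with a median of −0.06 (percentile 39.0) and a mean of 0.80.

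The type I interferon list had 6 of 23 genes higher and none lower (percentile 100), such as Cxcl10 (3.75-fold), Ifi44 (2.94-fold), Oas2 (2.81-fold) and Oasl2 (2.70-fold). The interferon-gamma list had a median of 0.11 (percentile 93.9), with Nos2, the inducible nitric oxide synthase (3.52-fold), Iigp1 (2.95-fold) and Gbp6 (2.76-fold) higher among 19. Cell cycle genes were higher for 16 of 25 (percentile 100): Kif11 by 4.60-fold, Nusap1 by 3.91-fold, Mki67 by 3.75-fold and Ccna2 by 3.53-fold. The neutrophil and basophil markers, which had medians of 4.54 and 3.85, were higher on the same array. Immediate early genes had a median of 0.19 (percentile 99.4), with Atf3 3.32-fold, Ier3 3.19-fold and Dusp1 2.11-fold higher and 2 of the 14 genes lower, Hspa1a and, named after its value was seen, Egr2 (2.07-fold). Medians were 0.23 (percentile 99.86) for glycolysis, −0.17 (percentile 8.23) for oxidative phosphorylation and −0.21 (percentile 5.86) for ribosomal protein genes, with no member past 2-fold. Reference genes had a median of −0.07 (percentile 50.7), whose sign differed between settings, with Actb at −0.25 and Gapdh at 0.14.

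With normexp, genes at least 2-fold higher at day 63 than in normal mice numbered 291 and genes at least 2-fold lower at day 63 than in normal mice 231, and Arg2, Ccl17, Il6, Ifi44, Iigp1, Derl3, Sdc1, Tlr3, Gcsam, Itga2b, Treml1, C1qa, Ccr3, Dtx1, Klri1 and Upb1 were under 2-fold, as was Gbp6 when probes were averaged. Medians with normexp were 1.97 for the basophil and 3.79 for the neutrophil markers.

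**Figure D2:**
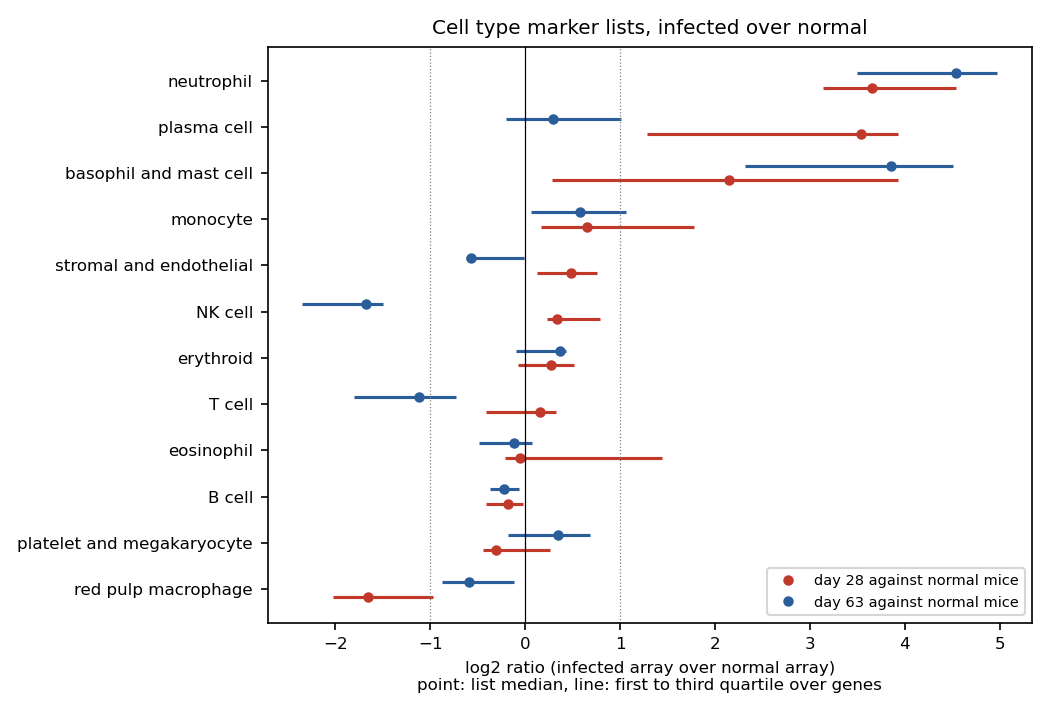
Median log2 ratio (points) and range from the first to the third quartile over genes (lines) of 12 lists of markers of other cell types, as the log2 ratio of an infected array over the normal array on the horizontal axis, with day 28 in red, day 63 in blue and dotted lines at 2-fold. Neutrophil markers lie at 3.66 and 4.54, plasma cell markers at 3.53 and 0.30, NK cell markers at 0.34 and −1.68, and red pulp macrophage markers at −1.65 and −0.59 for day 28 and day 63.

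Both infected arrays were compared with the same normal array, and 16590 genes were measured in both comparisons. At least 2-fold higher in both were 346 genes, of 729 and 676, and lower in both were 192, of 700 and 524. Independent lists of these sizes would share 29.7 and 22.1 genes, and in 100 simulations of arrays without differences, with spot error only and the normal array shared, means of 1.21 and 2.39 genes were shared. The normal group had 1 array and could not be split, so part of the excess may come from that array. Opposite directions, which a shared normal array makes rarer, were seen for 18 genes higher at day 28 and lower at day 63, with 23.03 for independent lists, and for 16 the other way round, with 28.5. The simulations without differences gave a mean of 0.28 for both kinds together.

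The comparison of day 63 with day 28 asked how the later infected array differed from the earlier one. Interferon-induced genes were lower at day 63, with a type I list median of −1.96 and Ifi44 10.7-fold lower. Plasma cell and NK cell genes were lower too, Jchain by 19.1-fold and Gzmb by 8.72-fold. Arg1 was 66.7-fold higher. Immediate early genes, genes of MHC class II and of the cDC1 subset, and markers of basophils and of red pulp macrophages were higher, with list medians of 1.68, 0.75, 0.89, 2.20 and 1.13.

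Of 16982 genes measured, 681 were at least 2-fold higher at day 63 than at day 28 and 639 at least 2-fold lower, 90 and 74 of them as bounds, and 117 and 148 differed at least 4-fold. Which direction held more genes depended on scaling: with scaling to the array median 590 were at least 2-fold higher and 768 at least 2-fold lower. Among genes ranked by the rule for named genes, the largest ratios upward were those of Arg1, Stfa3 (29.1-fold), Saa3 (27.8-fold), Stfa1 (25.8-fold) and Cstdc5 (18.4-fold). Of these, the Stfa and Cstdc genes are near-identical copies. The largest downward were those of Exph5 (33.9-fold lower), Cma1, a chymase (21.5-fold), Nxph1 (21.1-fold), Jchain and Tnfrsf17 (18.3-fold). Exph5 and Nxph1 were not well above background on the normal array. Their log2 levels were 2.65 and 0.04 on the day 28 array and −2.43 and −4.36 on the day 63 array.

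The type I interferon list had 18 of 23 genes lower and none higher (percentile 0), with Ifit3 6.53-fold and Rsad2 5.55-fold lower and Oasl1 at −2.32 on the log2 scale. The interferon-gamma list had 10 of 19 lower, with a median of −1.31 (percentile 0): Iigp1 by 6.23-fold, Gbp4 by 4.08-fold and Gbp6 by 4.03-fold. Its only member at least 2-fold higher was Nos2 (5.21-fold). The MHC class I list had a median of −0.45 (percentile 0.05), with Tap1 1.98-fold and H2-K1 1.95-fold lower and no gene past 2-fold. Neutrophil markers, by contrast, had a median of 0.31 (percentile 99.7), with Mmp8 7.74-fold, Lcn2 2.47-fold and the chemokine receptor gene Cxcr2 2.24-fold higher among 12. Plasma cell and NK cell markers went the way of the interferon lists, with medians of −2.24 and −2.56.

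The MHC class II list had 4 of 15 genes higher and none lower (percentile 100): Ifi30, a lysosomal thiol reductase, by 2.43-fold, H2-Aa by 2.27-fold, H2-Oa by 2.16-fold and H2-DMb2 by 2.10-fold, with H2-Ab1 at −0.02. The core dendritic cell list had a median of 0.50 (percentile 100), with Flt3 3.16-fold, Adam19 2.72-fold and Btla 2.28-fold higher among 18. The log2 ratios were 0.54 for Zbtb46, 0.80 for Ccr7 and −0.36 for Itgax. The cDC1 markers had 7 of 14 genes higher (percentile 100), such as Tlr11 (3.80-fold), Cadm1 (3.17-fold), Clec9a, a receptor for dead cells (3.14-fold), and Gcsam (2.57-fold). Batf3 was higher by 1.14 on the log2 scale and Irf8 stood at −0.08. The cDC2 markers had a median of 0.26 (percentile 98.9), with Clec4a4 2.96-fold higher, Mgl2 2.45-fold lower and Irf4 at −0.66. Plasmacytoid markers had a median of 0.02 (percentile 49.3), whose sign differed between settings, with Dntt 2.64-fold higher, Klk1 2.52-fold lower and Siglech at −0.06. In the costimulation list, Ccl17 was 5.91-fold, Tnfsf9 2.98-fold and Cd86 2.95-fold higher and Il15ra 2.02-fold lower, with a median of 0.40 (percentile 99.96). The probes of Il15ra disagreed. Log2 ratios were 0.10 for Cd40, 0.29 for Cd80, 0.01 for Cd274 and 0.41 for Pdcd1lg2.

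Immediate early genes were higher for 10 of 14 members and lower for none (percentile 100): Ier3 by 10.3-fold, Fosb by 9.91-fold, Egr1 by 9.41-fold and Atf3 by 9.06-fold. Proinflammatory genes had 8 of 19 higher and 2 lower, with a median of 0.65 (percentile 100): Ptgs2 12.4-fold and Cxcl2 7.79-fold higher, and Ccl5 5.19-fold lower. Regulatory mediators had a median of 0.42 (percentile 99.95), with Socs3 2.52-fold and Ahr, the aryl hydrocarbon receptor, 2.45-fold higher and Lgals1 2.80-fold lower, and Il10 at 0.76. The type 2 response list had a median of 0.51 (percentile 100), with Chil3 6.08-fold and Mrc1 5.27-fold higher among 5 of 14. Macrophages and other myeloid cells also carry these transcripts, and medians in this comparison were 1.13 for red pulp macrophage and 0.31 for neutrophil markers. Pattern recognition receptors had a median of 0.50 (percentile 100), with Clec4n 3.19-fold higher and the RNA sensor gene Ddx58 2.51-fold lower among 7 higher and 1 lower of 25.

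Cell cycle genes had a median of −0.47 (percentile 0) with no gene past 2-fold. The unfolded protein response list had a median of −0.18 (percentile 5.40), with Derl3 4.74-fold and Creld2 2.69-fold lower among 4 of 15. The plasma cell markers moved with it, 7 of 9 lower with a median of −2.24 (percentile 0): besides Jchain and Tnfrsf17, Mzb1 by 6.48-fold and Sdc1 by 5.29-fold. All 12 NK cell markers were at least 2-fold lower, with a median of −2.56 (percentile 0), Klra7 by 8.02-fold. T cell markers were lower for 8 of 15, with a median of −1.04 (percentile 0): Cd247 by 8.12-fold and Lck by 6.33-fold, with Cd3e at −0.26. Basophil markers were higher for 8 of 10 (percentile 100): Prss34 by 7.62-fold, Mcpt8 by 5.55-fold, Fcer1a by 5.20-fold and Ms4a2 by at least 5.02-fold. Red pulp macrophage markers were higher for 8 of 14 (percentile 100), Mertk by 5.20-fold, Cd163 by 4.24-fold and Vcam1 by 3.68-fold, and Siglec1 was 2.78-fold lower.

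Eosinophil markers had a median of −0.51 (percentile 0.14), with Epx lower by at least 4.31-fold and Prg2 2.48-fold lower. Monocyte markers had a median of 0.08 (percentile 82.2), whose sign differed between settings, with Ly6c1 5.82-fold and Fcgr1 2.88-fold lower and Cd14 2.31-fold higher. Stromal and endothelial markers had a median of −0.85 (percentile 0.01), with the collagen gene Col1a1 2.66-fold and Sparc 2.69-fold lower and Cdh5 4.72-fold higher. Platelet markers had a median of 0.52 (percentile 98.8), which was negative with normexp, and erythroid markers 0.04 (percentile 38.8), whose sign differed between settings and whose mean was −0.03. B cell markers had a median of −0.10 (percentile 13.9) with no gene past 2-fold. Medians were 0.10 (percentile 91.2) with a mean of −0.02 for glycolysis, −0.14 (percentile 16.6) for oxidative phosphorylation and 0.19 (percentile 99.5) for ribosomal protein genes. Reference genes had a median of 0.03 (percentile 71.7), whose sign differed between settings, with Actb at −0.55 and Gapdh at −0.24.

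With normexp, genes at least 2-fold higher at day 63 than at day 28 numbered 292 and genes at least 2-fold lower at day 63 than at day 28 numbered 384, and Ccl17, Cd163, Ms4a2, Epx, Cxcr2 and Il15ra were under 2-fold, as was H2-DMb2 with scaling to the array median. The basophil median was 1.12 in that setting.

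**Figure D3:**
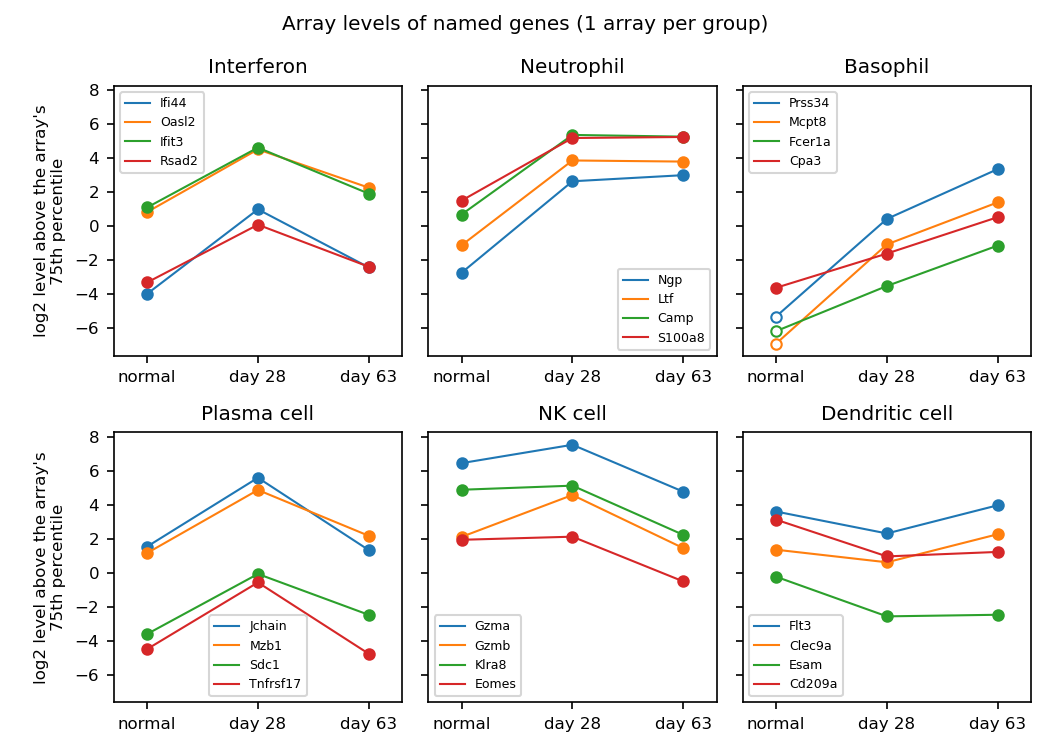
Level of 24 genes on the normal, day 28 and day 63 arrays, as the log2 signal above the array's 75th percentile on the vertical axis, in 6 panels by gene group; each line is a gene, each point is 1 array, and open points were not well above background. Ngp stands at −2.73, 2.65 and 3.01, Ifi44 at −3.98, 1.00 and −2.42, Jchain at 1.54, 5.59 and 1.33, and Flt3 at 3.60, 2.31 and 3.97 on the normal, day 28 and day 63 arrays.

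Lists share genes, such as Arg1, Chil3, Ccl17, Cxcl10, Derl3, Xbp1 and Cd209a, so their medians are not independent. Of the 96 list comparisons, medians lay in the upper 2.5% of random lists for 13, 15 and 15 lists and in the lower 2.5% for 10, 7 and 9, at day 28, at day 63 and between the infected arrays. The list of 11 immunoglobulin constant region genes gave no value, since none of its genes was named here. Of called genes with several probes above background, 183 of 223, 153 of 171 and 198 of 230 had all probes going the same way in these 3 comparisons. Probes of Gapdh and Siglech disagreed in direction in each comparison, and those of Cd80 and Klra8 at day 28 against normal.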

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

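The tests of scaling in the first and second patterns, of the neutrophil share against the interferon genes, and of the dendritic cell and B cell shares were chosen only after the results were seen, as was the reading of the basophil test.

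Type I interferon genes stood higher on the day 28 array, with a list median of 2.56. Cross-hybridisation of single probes is argued against, since other probes of 6 of these genes had a median log2 ratio of 2.44 with a first quartile of 1.85, and scaling or background is argued against by the lowest list median over those alternatives, 2.31. A larger share of neutrophils as the whole cause is argued against, since at day 63 against day 28 the interferon list stood at −1.96 with its upper quartile at −1.24, while neutrophil markers stood at 0.31. A response to infection may account for the pattern, as a hypothesis found and tested on the same arrays. Plasma cell and NK cell markers went the way of the interferon list. Their medians were 3.53 and 0.34 at day 28 against normal and −2.24 and −2.56 at day 63 against day 28. Shares of these and other cells that respond to interferon, and the handling of the single samples, were not tested and stay open.

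Neutrophil and basophil markers were higher on both infected arrays, and the abundant neutrophil transcripts S100a8 and S100a9 stood at log2 levels of 1.51 and 3.18 on the normal array, 5.19 and 6.65 at day 28 and 5.25 and 6.83 at day 63, each above the array's 75th percentile. Scaling is argued against, since no scaling alternative moved these medians by more than the replicate-spot SD of a ratio. The background step mattered more. The lowest neutrophil or basophil median over the scaling and background alternatives was 1.09, that of basophils with normexp at day 28, against 2.14 as reported. Neutrophils among the sorted cells stay open as a possible explanation: a second list of 22 neutrophil genes had medians of 0.64 at day 28 and 1.28 at day 63, of which the lower lay between the bounds of 0.5 and 1 set before the test, and 16 of its genes already stood above the normal array's median level. The median level on that array was −0.26 for this second list and −0.95 for the first neutrophil list, a smaller gap than between the basophil lists given next. For basophils the second list had medians of 0.27 over 14 genes at day 28 and 0.46 over 15 genes at day 63. Both lay under the bound of 0.5 written beforehand as evidence against basophils. After the result was seen that bound was judged wrong, because 10 of the second list's genes already stood above the normal array's median level. The second list's median level there was −0.93, against −4.89 for the first basophil list. These are levels of different probes, and whether a small share of basophils would be hidden was not tested, so basophils stay open. A gate on CD11c would be meant to leave out both cell types but is not given, 11 of 12 neutrophil and 6 of 10 basophil markers were already well above background on the normal array, and a response of the dendritic cells themselves stays open as untested.

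MHC class II and dendritic cell core genes were lower on the day 28 array. A lower share of dendritic cells among otherwise alike cells would raise the markers of every other cell type, and is argued against, since red pulp macrophage markers had an upper quartile of −0.97 while neutrophil markers had a lower quartile of 3.14. Fewer B cells are argued against, since the B cell markers had a lower quartile of −0.41 against a class II median of −1.02. Red pulp macrophage markers and immediate early genes took the course of the class II list. Medians were −1.65, −1.57 and −1.02 at day 28 against normal and 1.13, 1.68 and 0.75 at day 63 against day 28. A share of macrophages or sample handling was not tested as a cause. A share of dendritic cells that differed together with the makeup of the other cells may still play a part and was not tested, nor was a response to infection, the difference the design names.

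Among the probes without a gene name, which the comparisons did not use, 566 of 8670 were at least 2-fold higher at day 28 than in normal mice and 331 of 8859 at day 63, and 318 and 232 were at least 2-fold lower.

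For 7 named genes the ratios to normal passed 2-fold in opposite directions at day 28 and day 63, and with 1 array per group the difference was not tested. Arg1 had log2 ratios of −1.80 at day 28 and 4.26 at day 63. Atf3 had −1.45 and 1.73, Dusp1 −1.06 and 1.08, and Ier3 −1.70 and 1.67. Cma1 had 1.95 and −2.47, Gzma 1.08 and −1.68, and Klrg1 1.65 and −2.54. With normexp at day 28, Arg1 stood at −0.64 and Gzma at 0.91, under 2-fold. Scaling to the array median, which shifted the median of all genes at day 28 by 0.0885, would put Dusp1 under 2-fold as well, and the alternatives were not run for all of these ratios.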

How the results depend on the processing

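The counts without cell type marker genes, the counts of genes whose probes all went the same way and the values of the 5 added lists were chosen only after the results were seen. No paired analysis was possible because each group had 1 array. Of the alternative counts, 61 lay within 1.5 times the reported one, including those of both added settings, and 11 did not. Without marker genes, a setting within that bound, the counts were 712, 685, 685, 498, 655 and 602, in the order day 28 higher and lower than normal, day 63 higher and lower than normal, day 63 higher and lower than day 28. The marker lists hold too few genes to take a count out of that bound, and other genes of the same cell types stayed counted. This setting therefore cannot show how far cell makeup accounts for the counts. The 11 counts outside the bound were the 6 with normexp and 5 without a filter on dim probes. With normexp the counts in that order were 386, 248, 291, 231, 292 and 384, and without a filter the first 5 were 1174, 1301, 1152, 948 and 1229. An offset shrinks ratios of dim probes by construction and leaving out the filter lets dim genes enter without bounds, but no test was made of how far this accounts for the counts. Among genes past 2-fold, the share of higher ones at day 28 against normal ranged from 47.4% without a filter on dim probes to 60.9% with normexp, against 51.6% as reported. At day 63 against day 28 it ranged from 43.2% with normexp to 57.1% without a filter, also against 51.6%, with 43.4% for the array median, so which direction held more genes was not settled in either comparison. Quantile normalization gave 632 higher and 699 lower genes at day 63 than at day 28 and the authors' series matrix 643 and 694, and normexp moved the median of all genes at day 63 against day 28 by −0.127. Of 268 named ratios past 2-fold, 220 stayed past it under every setting that gave a value, with 12 not measured above background on both arrays, and 225 with normexp, and no named gene past 2-fold changed sign. Among list medians, 785 moved by less than the replicate-spot SD of a ratio, 77 moved by more and 2 reversed; for the added lists 122 and 13. Array median and 75th percentile of detected probes shifted list medians by less than that SD, the former with sign changes near 0. Signal over background limits the dim genes, for which ratios are bounds or depend on the background step.

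Medians that moved follow as log2 ratios, with the causes not tested. With normexp at day 28 against normal, MHC class II stood at −0.88, proinflammatory genes at −0.24, type 2 response at −0.29, type I interferon at 2.31, interferon-gamma at 1.40, cell cycle at 1.24, immediate early genes at −1.41, plasma cells at 2.40, neutrophils at 3.41, eosinophils at 0.11, macrophages at −1.47, basophils at 1.09, platelets at −0.0941 and stromal cells at 0.17. With normexp at day 63 against normal, regulatory mediators stood at 0.25, type I interferon at 0.52, cell cycle at 0.95, T cells at −0.82, NK cells at −1.84, neutrophils at 3.79, erythroid cells at 0.0302, basophils at 1.97 and stromal cells at −0.38, and platelets reversed to −0.0622. With normexp at day 63 against day 28, cDC1 stood at 0.61, pattern recognition receptors at 0.26, proinflammatory genes at 0.53, regulatory mediators at 0.23, type 2 response at 0.29, reference genes at 0.18, immediate early genes at 1.82, T cells at −0.75, plasma cells at −1.88, NK cells at −2.41, macrophages at 0.98, erythroid cells at −0.11, basophils at 1.12 and stromal cells at −0.61, and platelets reversed to −0.0243.

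Without a filter on dim probes, medians at day 28 were −0.68 for proinflammatory genes, −0.14 for regulatory mediators, 1.43 for interferon-gamma, 2.74 for plasma cells, 2.33 for basophils and −0.18 for platelets, at day 63 4.26 for basophils and −0.43 for stromal cells, and between the infected arrays −1.15 for interferon-gamma and −0.64 for stromal cells. With genes above background on both arrays, they were −0.14 for regulatory mediators and 1.15 for basophils at day 28, 3.05 for basophils and 0.20 for platelets at day 63, and −0.36 for eosinophils between the infected arrays. With the mean of probes, cDC2 stood at −0.61 at day 28, and between the infected arrays cDC1 stood at 1.03, MHC class II at 0.63, costimulation at 0.51, NK cells at −2.72 and stromal cells at −0.99.

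With outlier-marked spots kept, platelets stood at −0.18 at day 28, monocytes at 0.24 and stromal cells at −0.43 at day 63, and monocytes at −0.0418 and stromal cells at −0.63 between the infected arrays. With quantile normalization, ribosomal proteins stood at −0.0479 at day 63 and at 0.30 between the infected arrays, and platelets at 0.39. With the authors' series matrix, platelets stood at −0.13 at day 28, ribosomal proteins at −0.0236, monocytes at 0.25 and stromal cells at −0.43 at day 63, and between the infected arrays type 2 response at 0.38, ribosomal proteins at 0.31, reference genes at 0.15, T cells at −1.16, monocytes at −0.0396, platelets at 0.39 and stromal cells at −0.64. Medians near 0 changed sign between settings without having passed a threshold: MHC class I at day 63, eosinophils and regulatory mediators at day 28, erythroid, monocyte and plasmacytoid markers between the infected arrays, and reference genes in the 3 comparisons.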

Other observations

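The glucocorticoid, Notch and hypoxia lists, the second neutrophil and basophil lists and all tests on them were chosen only after the list medians and the highest-ranked genes had been seen. For these 3 hypotheses the bounds were written before the test results were seen, the genes that had raised each question were left out of its test, and all 3 met their predictions. Many of the 32 fixed lists with a value also passed these bounds. At day 63 against day 28, 15 lay in the upper 2.5% of random lists. Against normal, 10 at day 28 and 7 at day 63 lay in the lower 2.5%. Meeting the bounds therefore says little about a specific response.

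Of 15 genes that glucocorticoid hormones induce in many cell types, 9 were at least 2-fold higher at day 63 than at day 28 and none lower. These 9 include the 4 genes that had been seen first. Klf9, a transcription factor, had a log2 ratio of 2.63, the metallothionein gene Mt2 1.62, the clock gene Per1 1.51 and Ddit4 1.33, and Fkbp5, Il1r2, Dusp1 and Cd163, which had been seen first, had 2.94, 3.61, 2.14 and 2.08. Without these 4 genes, the median of the 11 others was 0.42, at percentile 99.87 of matched random lists. The values are consistent with a glucocorticoid response on the day 63 array, as a hypothesis, and Tsc22d3 and Sgk1, common targets of the hormone, had log2 ratios of 0.36 and 0.19. Other signals induce several of these genes. Cd163 is also in the red pulp macrophage list and Dusp1 in the immediate early list, with medians of 1.13 and 1.68 in this comparison. Neutrophil markers, such as Mmp8, were also higher at day 63 than at day 28, so a difference in cell makeup or handling was not excluded.

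Of 14 genes induced by low oxygen, 3 were at least 2-fold higher at day 63 than at day 28 and none lower: Egln3 by a log2 ratio of 1.90, Hilpda by 1.85 and Vegfa by 1.45. Ndrg1 had 0.98 and Pfkfb4 −0.42, and 3 of the 14 genes were below 0. The glycolysis list, which also holds Slc2a1, had a median of 0.10 (percentile 91.2), a mean of −0.02 and no gene past 2-fold. Without Slc2a1, which had been seen first, the 13 genes had a median of 0.34 at percentile 98.36, which is consistent with a hypoxia response as a hypothesis. Neutrophil markers and immediate early genes also had positive medians in this comparison, 0.31 and 1.68, so cell makeup or handling was not excluded.

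Esam and Dtx1, lower on both infected arrays, and Clec4a4, lower at day 28 but with a log2 ratio of 0.14 at day 63, depend on Notch signals in splenic dendritic cells and raised the question whether other Notch targets were lower on the infected arrays. Without Dtx1, the 9 measured targets stood at percentile 1.18 of matched random lists on 1 infected array and 0.07 on the other, with Hes1 at −0.99 and −0.88, Hey1 at −0.86 and −0.36 and Hes5 at −0.51 and −0.66 at day 28 and day 63. None of these 9 was 2-fold lower at day 28, and 2 were at day 63, Nrarp and Gata3. The percentiles of 1.18 and 0.07 are consistent with slightly lower Notch target expression, as a hypothesis. Nrarp and Notch1 went the other way at day 28, with 0.66 and 0.81, and T cell genes in the list, such as Gata3 at −2.01, stood lower at day 63 together with the T and NK cell markers, so a smaller share of those cells stays open. Between the infected arrays the list had a median of 0.19, whose sign differed between settings, and a mean of −0.39.

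The second neutrophil list held genes that differed widely at day 28 and day 63. Ctsg, the cathepsin of neutrophil granules, had log2 ratios of 2.72 and 3.67 and Cd177 2.70 and 3.69, while Csf3r, the receptor of the neutrophil growth factor, had 0.13 and −0.08. At day 63 against day 28 this list had a median of 0.50, and the second basophil list one of −0.09 with a mean of 0.19.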
